A study of Homo sapiens with 8 samples.

How the data were processed

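Gene expression was measured on 8 Agilent 2-colour arrays, 4 for each of 2 stable FUT8 knockdown clones of the human lung adenocarcinoma line CL1-5. Each array carried knockdown cDNA and cDNA of the vector control line CL1-5/Control. Per the labels, the knockdown cDNA carried Alexa647, read in the red channel, and the control cDNA carried Alexa555, read in the green channel, on every array. No array had the dyes exchanged, so a dye effect does not cancel in the ratio of a clone over control. It cancels only in the difference between the clones.

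The authors scanned the arrays and deposited 1 file per array from Agilent Feature Extraction 10.5.1.1, per the file headers. The intensity values in those files are median spot signals and median local backgrounds of each channel, not corrected or normalized, per the file headers. The log10 ratio of red over green in the same files had been made by the authors' Feature Extraction run after background subtraction and dye normalization, per the file headers. The series value table deposited by the authors holds a log2 ratio for each probe. Its scale and direction were found by setting each column against the scanner ratio of the same array, turned to log2. Over 42405 probes the correlation was 0.996 to 1.00, with slopes of 1.00, so the table runs red over green. Its column medians lay between 0.01 and 0.07. Whether any centring was done beyond that of Feature Extraction is not given in the sources used here. Other flags used from the files mark spots as well above background, saturated, non-uniform or population outliers.

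The design had assumed mean spot signals, but the files hold median signals, and these were used. Background was corrected with normexp and an offset of 50, and red over green log2 ratios were normalized within each array by loess, with control spots and outlier spots at weight 0. Spots marked as non-uniform or as population outliers were removed. Saturated spots would have been kept, but none occurred. Removal of spots leaves some genes with values from fewer than 4 arrays of a clone, and n is then given. Replicate spots of a probe were averaged. These steps used limma 3.58.1 in R 4.3.3, with statmod 1.5.0, jsonlite 2.0.0 and the data.table package of version 1.17.8.

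Each array held 62976 spots, of which 4259 were controls, and 42405 distinct probes. Gene names came from the RefSeq transcript accession that the files give for a probe, matched without version to the RefSeq gene list of assembly GRCh38.p14. The array design names build hg19, so no coordinates of that list are given. Of the probes, 24910 were named by 1 gene and 17495 were left unnamed, among them 8263 lincRNA probes and 953 probes with a RefSeq-type accession not in that list. The named probes covered 19102 genes, 4835 of them with 2 or more probes. A gene was represented by its brightest probe over the 8 arrays, and other probes are given for the named genes where they differed most. A gene was kept where that probe was well above background in the red channel on all 4 arrays of a clone or in the green channel on at least 4 of the 8 arrays. This left 17076 genes. Where a probe was not well above background in the red channel on any array of a clone, the change is given as a bound. The bound sets the control mean against, per array, the higher of the probe's own signal and the lowest signal among probes well above background, after loess and Aquantile, and it is open to dye bias. It equals the fitted value where the probe's own signal was the higher on each array.

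One coefficient per clone was fitted to all 8 arrays with lmFit and eBayes, so that both clones shared 1 estimate of the spread per gene. The tests were two-sided: each clone's log2 ratio against 0, and shFUT8-1 minus shFUT8-2. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. A gene was called in both clones when it passed in each with the same sign. Because the ratio is set against 0, the spread of the control line enters only through the control cDNA on each array. The labels call the 4 arrays of a clone biological replicates but do not say whether separate cultures were grown or whether control RNA was shared between arrays. If they were not separate cultures, the p-values measure only the spread between these samples, which may be technical.

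A total of 23 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, where a list had at least 5 measured genes. Calls were repeated with the estimated correlation. The lists cover fucosylation, N-glycan processing, epithelial and mesenchymal markers, integrins, matrix genes and proteases, growth factor receptors and TGF-beta response. They also cover replication, interferon and antigen presentation, inflammation, stress pathways, metabolism, p53 targets, ribosomal proteins, surface adhesion genes, lung differentiation, and markers of leukocytes and of fibroblasts and endothelium. The lists, the settings of the fit, the alternative settings other than 2 pairs of left-out arrays and most of those for the correlation of the clones, and the rule for naming genes were written before the data were examined.

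The rule names 10 genes per direction for each clone, with the largest change among called genes of the same sign on all 4 arrays. It names 10 per direction for both clones, by the smaller of the 2 changes and with the same sign on all 8 arrays. It names 10 per direction for the clone difference, among called genes whose 4 arrays of one clone all lay above the 4 of the other. For each list described it names up to 4 members with the largest mean change in absolute size over the 8 arrays, called or not. FUT4, GMDS, CDH1, CDH2, VIM, FN1, SNAI2, EGFR, ITGB1, TGFBR1, TGFBR2 and MET are named whatever their values, and FUT8 was to be named always. No probe was paired with the name FUT8 in the tables used, so FUT8 itself is not analysed here. Only genes with a gene symbol are named by the rule, and 1 gene that it names is not reported here.

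The comparisons of both clones share the control line. Unchanged clones were therefore simulated 50 times, once with control values fully shared by same-numbered arrays and once with the estimated correlation of such arrays. A deviation common to all 8 arrays was not simulated. The correlation and covariance of the clones were also recomputed from arrays of different replicate numbers in 6 splits. All 8 arrays were on 1 slide and in 1 scan. The arrays of shFUT8-1 filled the first of its rows and those of shFUT8-2 the other, so clone and slide row cannot be told apart, and a fit with slide as a block could not be made. The number of arrays limits the precision. Alternatives covered background correction, normalization within and between arrays, filters on dim probes, probes of a gene, the variance model, array weights, clones fitted alone, the deposited value table, the replicate number as a block, the gene list test, and leaving out each array. The number of calls of 2-fold or more was also recorded.

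The fits were tested on simulated data for the same 17076 genes with known changes. Of the genes changed in both clones, 83.6% were recovered at a log2 change of 0.5 and 100% at 1 and at 2. For the clone difference the shares were 61.2%, 100% and 100%. Among unchanged genes, 32 of 16646 were called in shFUT8-1, 8 of 16876 in shFUT8-2, 0 of 16646 in both clones and 12 of 16646 in the difference. The shifted gene list was found in the comparisons it was shifted in, and no other list was called. The simulated noise was independent between genes, so this does not show how often lists are called falsely where genes correlate.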

Results

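CL1-5 is a human lung adenocarcinoma line of high invasiveness, and FUT8 is the fucosyltransferase that adds core fucose to N-glycans. Stable clones shFUT8-1 and shFUT8-2 had been made with lentiviral short hairpin vectors and were compared with vector control cells, 4 arrays per clone. The comparison asks which transcripts differ when FUT8 is knocked down. On the arrays, 79.6% to 87.1% of spots were well above background in green and 79.5% to 84.7% in red, and no spot was saturated. Median signals were 243 to 631.5 in green and 378 to 758 in red. Correlations across genes between arrays were 0.644 to 0.850 within shFUT8-1 and 0.774 to 0.870 within shFUT8-2; genes are not independent replicates. Replicates 1 and 2 of shFUT8-2 had 3948 and 3040 spots set aside as outliers, against 756 to 1411 on the other arrays. FUT8 itself is not analysed here, so the knockdown was not checked on these arrays. All values below are log2 ratios of knockdown over control, with SD and n over arrays.

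In shFUT8-1, among genes with values of the same sign on all 4 arrays, the growth factor gene FGF7 rose most, by a log2 ratio of 6.17 ± 0.21 (SD, n = 4), which is 72.0-fold, with its other probe at 3.80. FGF7P3, an FGF7 pseudogene, rose by 3.94 ± 0.29, FBXO38, a subunit of ubiquitin ligases, by 2.08 ± 0.39, and ECSCR, an endothelial surface protein gene, by 2.06 ± 0.33. ATL1, RGCC, CHGB, SLC14A1, TGFBI and EP400 rose by 1.77 to 2.05. The largest fall was that of SPP1, which encodes osteopontin, at -7.44 ± 0.42, or 174-fold lower. DNER, a Notch-related surface protein gene, was at -5.32 ± 0.36, GALNT14, which starts O-glycan chains, at -4.89 ± 0.49, and AGR2, an endoplasmic reticulum disulfide isomerase gene, at -4.51 ± 0.33. FN1, encoding fibronectin, was at -4.45 ± 0.53 or 21.9-fold lower, and BACE2, SORL1, NPTX2, ADAMTSL3 and PARM1 were between -4.31 and -3.48, although the other ADAMTSL3 probe was at -2.14. Each of these genes had limma adjusted p-values of 1.13e-06 or less. Of 17076 genes tested, 7232 changed, 2817 up and 4415 down, and 544 of them by 2-fold or more, 80 up and 464 down. With median centring in place of loess, 7960 changed, and the share of rises was 57.2% against 39.0%, so the balance of directions depends on the normalization.

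In shFUT8-2, FGF7 again rose most, by 6.32 ± 0.10 (SD, n = 4) or 79.7-fold, followed by FGF7P3 at 3.51 ± 0.40 and ECSCR at 2.94 ± 0.35. TLR4, a receptor for bacterial lipopolysaccharide, rose by 2.78 ± 0.16, and TIMP3, an inhibitor of metalloproteinases, by 2.30 ± 0.19. FBXO38, KIAA0040, SLC14A1, STING1, which senses cyclic dinucleotides, and OAS2, an antiviral enzyme gene, rose by 2.03 to 2.29. Among genes with values of the same sign on all 4 arrays, DNER fell most, to -4.90 ± 0.13, with SPP1 at -4.38 ± 0.17 or 20.8-fold lower, NPTX2 at -4.22 ± 0.14 and FN1 at -3.86 ± 0.39 or 14.6-fold lower. BACE2, FAM184A, SORL1, PAG1, CALD1 and WWC1 were between -3.57 and -2.94, although another PAG1 probe was at -0.81. These genes had limma adjusted p-values of 1.92e-06 or less. GALNT14, with values on 2 arrays only, was at -4.94 ± 0.35 (n = 2). In all, 6683 genes changed, 2564 up and 4119 down, and 474 by 2-fold or more, 74 up and 400 down. Without replicates 1 and 2 of shFUT8-2, a setting chosen after seeing the data, 3684 genes changed in this clone.

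Changes were compared between the clones because both carry a knockdown of the same gene. Among the 20 genes named by the size of their change in both clones, from those with values of the same sign on all 8 arrays, EP400, a chromatin remodelling ATPase gene, stood at 1.77 ± 0.09 and 1.77 ± 0.22 (SD, n = 4 each) in shFUT8-1 and shFUT8-2. ATF2, a transcription factor gene, stood at 1.66 ± 0.17 and 1.78 ± 0.11, with its other probe at 0.71 and 0.65, and DNAJC15 at 1.72 ± 0.25 and 1.64 ± 0.29. Falls shared by both clones included those of LAMA3, a laminin chain gene, at -2.54 ± 0.22 and -2.71 ± 0.25, GPC4, a glypican gene, at -2.89 ± 0.37 and -2.72 ± 0.30, and ADD2 at -3.25 ± 0.43 and -2.92 ± 0.07. The other ADD2 probes were at -4.17 and -1.80 in shFUT8-1 and at -3.25 and -1.61 in shFUT8-2, and those of SLC14A1 between 1.21 and 1.90 and between 1.29 and 2.15. The rule left out GALNT14 and RGCC, which had values on 2 arrays of shFUT8-2 and stood at -4.89 and 2.02 in shFUT8-1 and at -4.94 and 1.78 in shFUT8-2. In red, DNER and GPC4 were well above background on 3 of 4 shFUT8-1 arrays, and with the scanner log ratios they stood at -7.13 and -4.59 there. For EP400, ATF2, DNAJC15, LAMA3, GPC4 and ADD2 the difference between the clones did not pass the test.

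A total of 4804 genes changed in both clones the same way, 1635 up and 3169 down, and 67 changed in opposite directions. Changes of 2-fold or more in both numbered 321, with 42 up and 279 down. Independent lists of these sizes would share 423 rises and 1065 falls. Simulated unchanged clones shared 0.02 genes when same-numbered arrays fully shared their control values. Across genes, the log2 ratios of the clones had Pearson r = 0.841, Spearman rho = 0.791 and a covariance of 0.135. Simulated unchanged clones with fully shared controls gave r = 0.501 and a covariance of 0.00385. Clones taken from arrays of different replicate numbers gave r of 0.768 to 0.825 and covariances of 0.129 to 0.141. The share of rises was 34.0%, against 44.4% with the scanner log ratios (2077 up, 2602 down) and 44.9% with the deposited value table (2152 up, 2645 down). Without replicates 1 and 2 of shFUT8-2 the number was 2904.

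**Figure D1:**
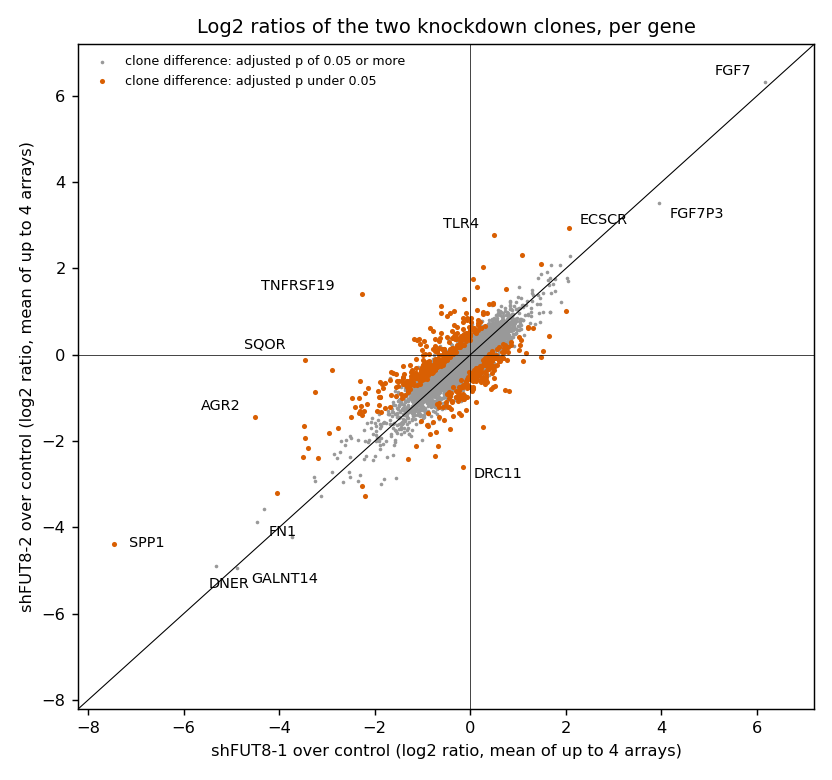
Each point is 1 of 17076 genes, with the log2 ratio over control in shFUT8-1 on the x axis and in shFUT8-2 on the y axis (means of up to 4 arrays) and the line of equal values. FGF7 lies at 6.17 and 6.32, SPP1 at -7.44 and -4.38, and the orange points are the 563 genes whose clone difference had an adjusted p under 0.05.

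**Figure D2:**
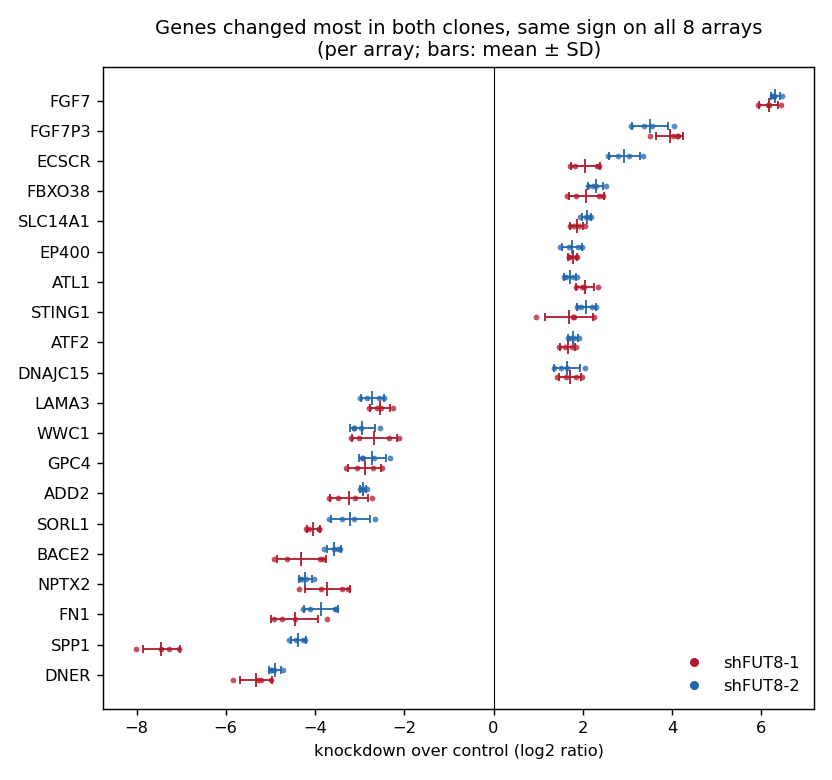
Log2 ratios of knockdown over control on each array (dots) with mean and SD (bars) for the 10 genes that rose and the 10 that fell most in both clones among genes with values of the same sign on all 8 arrays, shFUT8-1 in red and shFUT8-2 in blue. For SPP1 the 4 arrays of shFUT8-1 average -7.44 and those of shFUT8-2 average -4.38, and for FGF7 the clones overlap.

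Genes of glycan synthesis were examined because FUT8 acts on N-glycans. Of 32 measured genes of N-glycan processing, 19 fell, 0 rose and 13 did not pass in shFUT8-1, and 19 fell, 1 rose and 12 did not pass in shFUT8-2. MGAT4A, which adds an N-glycan branch, was at -1.44 ± 0.76 and -1.83 ± 0.29 (SD, n = 4 each). It was well above background in red on 1 of 4 shFUT8-1 arrays and 2 of 4 shFUT8-2 arrays, so the sizes depend on the treatment of background, and the deposited value table gave -3.10 and -3.82. The sialyltransferase genes ST3GAL5, whose product makes a ganglioside, and ST3GAL6 were at -1.35 ± 0.34 and -0.76 ± 0.18 in shFUT8-1 and at -0.93 ± 0.24 and -1.08 ± 0.15 in shFUT8-2. The Golgi mannosidase gene MAN2A1 was at -0.62 ± 0.13 and -0.71 ± 0.12. The list shifted downward in both clones (camera adjusted p = 0.000776 and 0.000723), with adjusted p = 0.357 and 0.382 with an estimated correlation. Of 19 genes of fucosylation and GDP-fucose synthesis, 3 rose and 6 fell in shFUT8-1 and 1 rose and 8 fell in shFUT8-2, and this list was not called (camera adjusted p = 0.823 and 0.899). GFUS, for the last step of GDP-fucose synthesis, was at -0.70 ± 0.15 and -0.48 ± 0.18, and the fucosidase gene FUCA1 at -0.62 ± 0.27 and -0.70 ± 0.22. FUT7 was at -0.55 ± 0.18 and -0.32 ± 0.12, and the fucokinase gene FCSK at -0.53 ± 0.24 and -0.28 ± 0.10. GMDS, which starts GDP-fucose synthesis, rose by 0.33 ± 0.12 and 0.28 ± 0.07, and FUT4 stood at 0.26 ± 0.28 (adjusted p = 0.0425) and 0.22 ± 0.13 (adjusted p = 0.0840). The counts of both lists were equal when adjusted over the list alone. The FUT4 call in shFUT8-1 and the FCSK and FUT7 calls in shFUT8-2 were lost under some settings, FUT4 and FCSK with single arrays left out.

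Epithelial markers were lower in shFUT8-1, where 16 of 31 measured genes fell and 1 rose (camera adjusted p = 0.0287, and adjusted p = 0.357 with an estimated correlation). In shFUT8-2, 11 fell and 2 rose, and the list was not called (camera adjusted p = 0.496). KRT19, a keratin gene, was at -1.90 ± 0.23 and -2.18 ± 0.42 (SD, n = 4 each), KRT8 at -1.13 ± 0.15 and -0.42 ± 0.09, and the splicing factor gene ESRP1 at -0.75 ± 0.40 and -0.66 ± 0.23. In red, ESRP1 and CDH1 were well above background on 3 of 4 shFUT8-1 arrays, and their sizes depend on the settings. ESRP1 ran from -1.48 to -0.59 in shFUT8-1 and from -1.15 to -0.55 in shFUT8-2. CDH1 ran from -0.93 to -0.25 and from -1.38 to -0.55. The desmosomal gene DSC2 was not well above background in red on any array. Its bound over the 4 arrays of a clone was at least 1.44-fold lower in shFUT8-1 and at least 1.70-fold lower in shFUT8-2, the latter equal to the fitted value. The fitted log2 ratios ran from -2.66 to -0.48 and from -2.51 to -0.72 over the settings, nearest to 0 without replicate 4 of shFUT8-1 and without replicate 2 of shFUT8-2. CDH1, encoding E-cadherin, was at -0.37 ± 0.30 (adjusted p = 0.0466) and -0.70 ± 0.40, and its call in shFUT8-1 was lost under 8 settings, among them leaving out replicate 2, 3 or 4 of shFUT8-1 or replicate 2 or 4 of shFUT8-2. Of 29 mesenchymal genes, 4 rose and 7 fell in shFUT8-1 and 8 rose and 10 fell in shFUT8-2 (camera adjusted p = 0.823 and 0.899). Besides FN1, the members that fell included S100A4, a calcium-binding protein gene, at -2.23 ± 0.20 and -2.40 ± 0.14, CALD1 at -1.87 ± 0.80 and -2.98 ± 0.25, and CDH2, encoding N-cadherin, at -1.51 ± 0.71 and -0.89 ± 0.34. VIM stood at 0.17 ± 0.26 (n = 3) and 0.11 ± 0.11 and SNAI2 at -0.34 ± 0.56 and -0.31 ± 0.05, neither passing the test. Some settings changed this: VIM passed as higher in both clones with median centring. SNAI2 passed as lower in shFUT8-1 without replicate 1 or 2 of that clone, and in shFUT8-2 with the clones fitted alone. Adjusted over the list alone, the counts were the same, except that 11 mesenchymal genes fell in shFUT8-2.

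Among 36 surface growth factor receptors, 18 fell and 1 rose in shFUT8-1 and 17 fell and 2 rose in shFUT8-2. PDGFRA was at -1.51 ± 0.26 and -1.07 ± 0.16 (SD, n = 4 each), FGFR2 at -1.31 ± 0.25 and -1.21 ± 0.31, FGFR1 at -0.94 ± 0.08 and -0.70 ± 0.14, RET at -0.73 ± 0.34 and -0.84 ± 0.31, and MET at -0.42 ± 0.06 and -0.78 ± 0.24. PDGFRA was well above background in red on 1 of 4 shFUT8-1 arrays, so the size of its fall depends on the treatment of background, and the scanner log ratios gave -3.76 and -2.29. TGFBR1 rose by 0.55 ± 0.33 and 0.50 ± 0.22, while TGFBR2 was at -0.42 ± 0.09 and -0.21 ± 0.14, its calls lost with median centring, and in shFUT8-2 also without replicate 1, 2 or 3 of that clone. Over the settings TGFBR1 ran from 0.43 to 1.08 in shFUT8-1 and from 0.31 to 0.88 in shFUT8-2. EGFR stood at 0.06 ± 0.09 and -0.07 ± 0.12 and did not pass, with its other probes between -0.44 and -0.02 in shFUT8-1 and between -0.62 and -0.19 in shFUT8-2. EGFR passed as higher in shFUT8-1 with median centring, and as lower in shFUT8-2 with the mean of all probes of a gene. The receptor list was called in both clones (camera adjusted p = 0.0287 and 0.00719), with adjusted p = 0.357 and 0.382 with an estimated correlation. Of 23 integrin subunits, 4 rose in each clone, and 8 fell in shFUT8-1 and 6 in shFUT8-2 (camera adjusted p = 0.730 and 0.899). ITGB5 was at -0.84 ± 0.20 and -1.05 ± 0.20, ITGB6 at -0.62 ± 0.34 and -0.80 ± 0.18, and ITGA2B at -0.62 ± 0.36 and -0.75 ± 0.26. ITGB4 was at -0.91 ± 0.51 in shFUT8-1, and its value of -0.25 ± 0.18 in shFUT8-2 did not pass, but the difference between the clones did not pass either. ITGB1, a known carrier of core fucose, stood at -0.01 ± 0.32 and -0.02 ± 0.21, and at 0.38 in shFUT8-1 with median centring, where it passed. The receptor and integrin counts were the same adjusted over the list alone.

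Of 31 collagens, laminins and basement membrane genes, 13 fell and 4 rose in shFUT8-1 (camera adjusted p = 0.0301, and adjusted p = 0.820 with an estimated correlation) and 14 fell and 5 rose in shFUT8-2 (camera adjusted p = 0.133). Besides LAMA3, COL6A3 was at -1.39 ± 0.49 and -1.78 ± 0.32 (SD, n = 4 each), LAMB2 at -1.14 ± 0.22 and -0.76 ± 0.12, and COL18A1 at -0.99 ± 0.20 and -0.89 ± 0.14, with the other COL6A3 probe at -0.18 and -0.36. The call of this list in shFUT8-1 was lost without replicate 2 or replicate 3 of shFUT8-1. Of 33 matrix proteases and inhibitors, 6 rose and 11 fell in shFUT8-1 and 4 rose and 9 fell in shFUT8-2 (camera adjusted p = 0.730 and 0.899). The protease genes ADAMTS1 and MMP15 were at -1.64 ± 0.11 and -1.45 ± 0.26 in shFUT8-1 and at -1.26 ± 0.23 and -1.09 ± 0.36 in shFUT8-2, and the protease inhibitor gene SERPINE2 at -1.04 ± 0.48 and -1.08 ± 0.04. Adjusted over the list alone, 16 matrix genes and 13 protease genes fell in shFUT8-1 and 15 and 9 fell in shFUT8-2, and the rises were the same. Of 33 surface genes of adhesion and metastasis, 5 rose and 14 fell in shFUT8-1 and 7 rose and 12 fell in shFUT8-2 (camera adjusted p = 0.730 and 0.899; 8 rose in shFUT8-2 adjusted over the list alone). In this list, the semaphorin co-receptor gene NRP1 was at -3.46 ± 0.31 and -1.93 ± 0.10, ALCAM at -1.19 ± 0.31 and -1.41 ± 0.26, PCDH7 at -0.88 ± 0.46 and -1.08 ± 0.32 (in red well above background on 3 of 4 arrays of each clone, and at -1.96 and -2.25 with the scanner log ratios), and CD44, the hyaluronan receptor gene, rose by 1.65 ± 0.20 and 0.43 ± 0.17. Of 30 TGF-beta response genes, 7 rose and 9 fell in shFUT8-1 and 8 rose and 11 fell in shFUT8-2 (camera adjusted p = 0.761 and 0.899; 9 rose in shFUT8-2 adjusted over the list alone). TGFBI rose by 1.78 ± 0.19 and 1.47 ± 0.44, while THBS1, encoding thrombospondin, was at -2.19 ± 0.75 and -0.89 ± 0.07 (other probe -1.25 and -0.53), and BAMBI, a decoy receptor gene, at -0.94 ± 0.31 and -0.96 ± 0.14.

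Of 63 ribosomal protein genes, 30 rose, 3 fell and 30 did not pass in shFUT8-1, and 22 rose, 3 fell and 38 did not pass in shFUT8-2. The list medians were 0.33 and 0.21 (camera adjusted p = 2.29e-09 and 2.04e-06), but neither was called with an estimated correlation (adjusted p = 0.820 and 0.941). The shFUT8-2 call was also lost with fry (adjusted p = 0.0657), with the scanner log ratios and with the deposited value table. Among 10000 random lists matched on brightness the medians lay at percentiles 100 and 99.97. Of the random medians, 95% lay between 0.01 and 0.17 and between 0.01 and 0.15. The random lists held genes drawn singly, which need not vary together as members of 1 list may, so these percentiles cannot decide on chance. The rises numbered 36 and 24 adjusted over the list alone. RPL22 rose by 0.93 ± 0.22 and 0.74 ± 0.11 (SD, n = 4 each), RPS18 by 0.90 ± 0.23 (n = 3) and 0.69 ± 0.14, and RPL21 by 1.03 ± 0.47 and 0.78 ± 0.34 (n = 3 each). RPL23 rose by 0.81 ± 0.50 and 0.65 ± 0.42 with n = 2 in each clone, and this call was lost in each clone with the scanner log ratios, in shFUT8-1 without its replicate 3 and in shFUT8-2 without its replicate 1. The RPL21 call in shFUT8-2 was lost without replicates 1 and 2 of that clone (0.38) and with a fixed replicate block. Over the settings the list median ran from 0.22 to 0.80 in shFUT8-1 and from 0.09 to 0.48 in shFUT8-2, highest with median centring in both and lowest without replicate 1 of shFUT8-1 and without replicates 1 and 2 of shFUT8-2. The list medians of single arrays ranged from 0.04 to 0.65, and ribosomal protein genes have many processed pseudogenes.

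**Figure D3:**
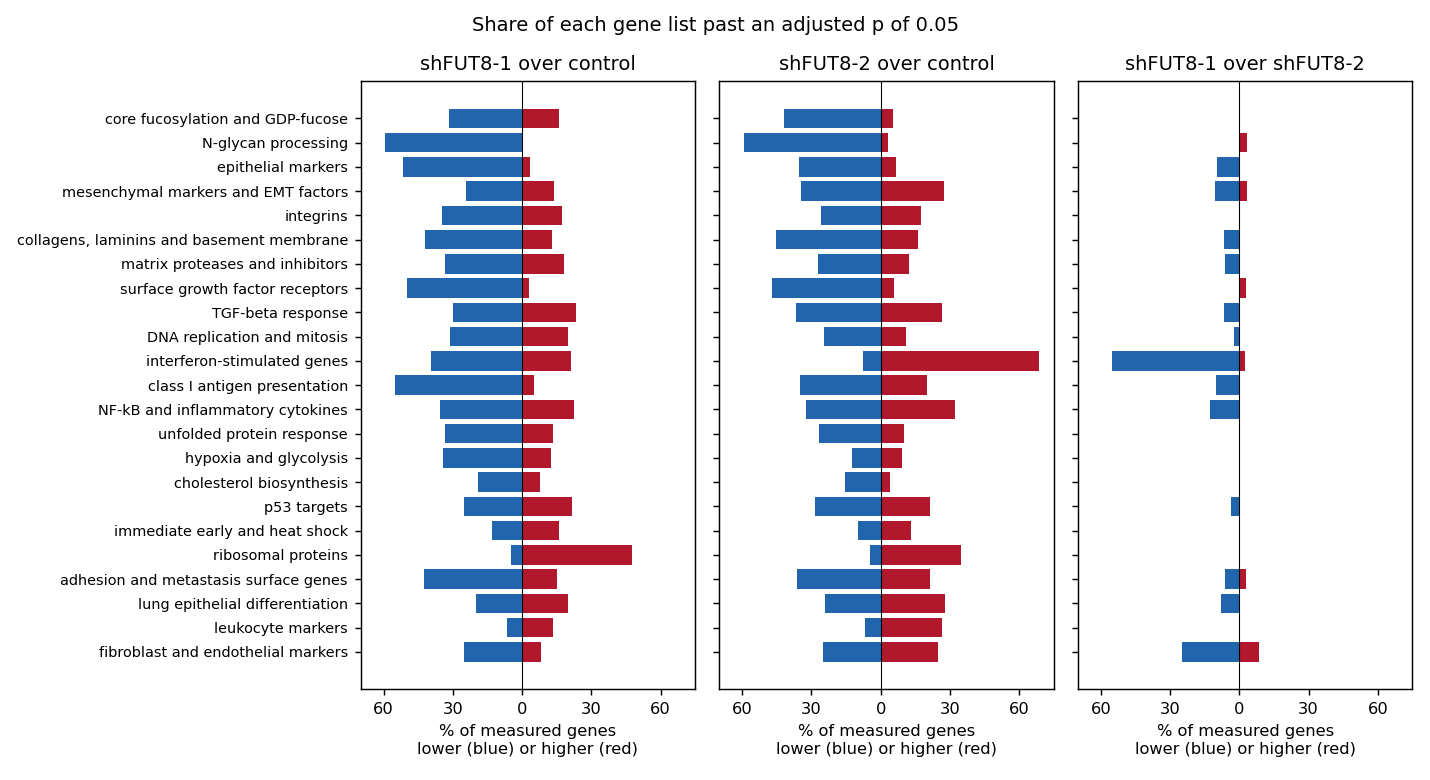
Bars give the percentage of measured genes of each of 23 lists that were lower (blue, to the left) or higher (red, to the right) at an adjusted p under 0.05, for each clone over control and for shFUT8-1 over shFUT8-2. Interferon-stimulated genes had 26 of 38 members up in shFUT8-2, and 21 of 38 were lower in shFUT8-1 than in shFUT8-2.

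The clones were also compared with each other, a contrast in which a common dye effect cancels. Interferon-stimulated genes, induced by interferon and double-stranded RNA, differed most among the lists: 21 of 38 were lower in shFUT8-1 than in shFUT8-2, 1 was higher and 16 did not pass, with a median difference of -0.59. The counts were 33 lower and 1 higher adjusted over the list alone. In shFUT8-2, 26 of them rose and 3 fell over control (median 0.41, camera adjusted p = 5.4e-10, and adjusted p = 0.382 with an estimated correlation). In shFUT8-1, 8 rose and 15 fell (camera adjusted p = 0.730); adjusted over the list alone, 29 rose and 3 fell in shFUT8-2, and 9 rose and 15 fell in shFUT8-1. The clone difference of the list had a camera adjusted p of 3.64e-31, and adjusted p = 0.0645 with an estimated correlation. OAS2 was at 0.26 ± 0.20 and 2.03 ± 0.17 (SD, n = 4 each), with its other probes at 0.38 to 0.75 and 2.05 to 2.84, the antiviral GTPase gene MX1 at -0.60 ± 0.18 and 1.13 ± 0.43, and USP18, which removes ISG15 from proteins, at -1.82 ± 0.12 and -0.77 ± 0.23 (n = 3). MX1 was well above background in red on 3 of 4 shFUT8-1 arrays, and at -1.52 there with the scanner log ratios. IFITM2 was at -1.30 ± 0.37 and -0.69 ± 0.18, and the exonuclease gene ISG20 rose by 1.06 ± 0.84 and 1.32 ± 0.19, and their differences between the clones did not pass. The OAS2 call in shFUT8-1 was lost without replicate 3 or replicate 4 of that clone.

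**Figure D4:**
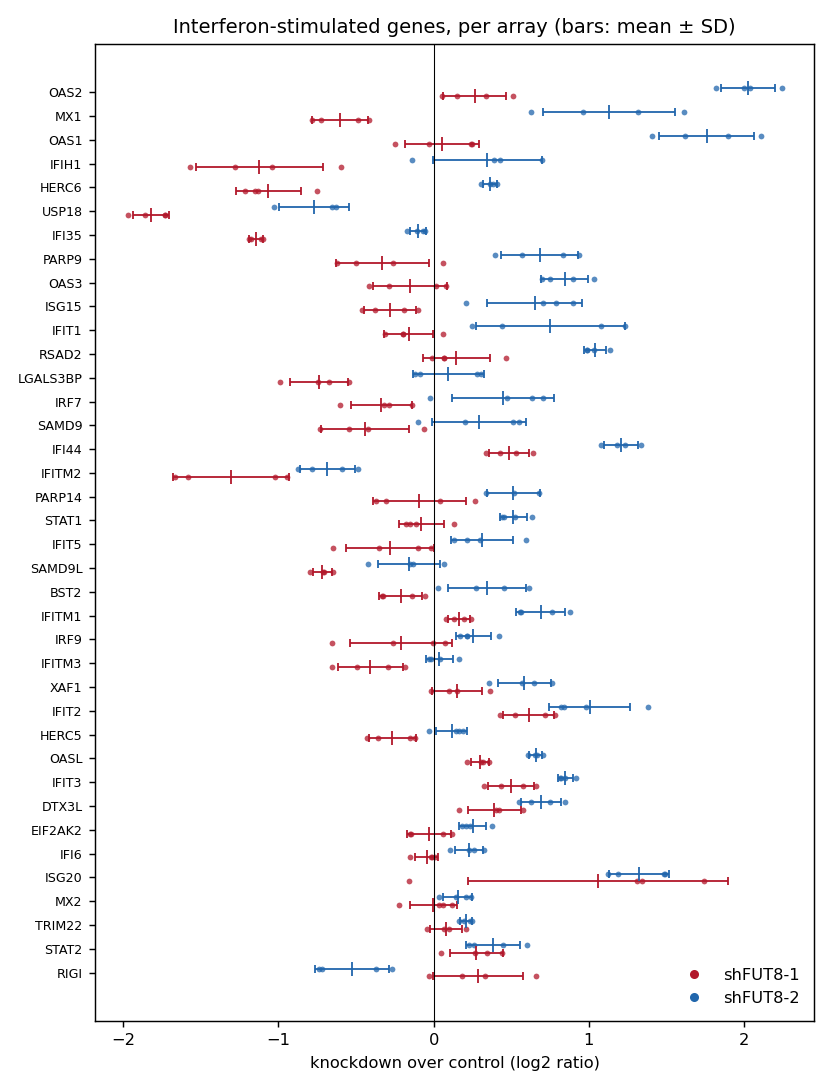
Log2 ratios of knockdown over control on each array (dots) with mean and SD (bars) for 38 interferon-stimulated genes, shFUT8-1 in red and shFUT8-2 in blue, ordered by the clone difference. OAS2 averages 0.26 in shFUT8-1 and 2.03 in shFUT8-2, and MX1 averages -0.60 and 1.13.

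Genes of class I antigen presentation also differed between the clones as a list (median difference -0.14, camera adjusted p = 0.000137, and adjusted p = 0.472 with an estimated correlation), with 2 of 20 genes lower in shFUT8-1 and 0 higher. Over the settings this median difference ran from -0.18 to -0.033. Over control, 11 fell and 1 rose in shFUT8-1 (camera adjusted p = 0.0287, and adjusted p = 0.820 with an estimated correlation), and 7 fell and 4 rose in shFUT8-2 (camera adjusted p = 0.899). The shFUT8-1 call was lost without replicate 2 of shFUT8-1 and with median centring. HLA-B was at -1.25 ± 0.52 and -0.61 ± 0.08 (SD, n = 4 each), HLA-C at -0.81 ± 0.22 and -0.51 ± 0.05 (n = 2), and the immunoproteasome gene PSMB10 at -0.63 ± 0.22 and -0.71 ± 0.14. For HLA-B, HLA-C and PSMB10 the difference between the clones did not pass. HLA-C was well above background in red on 3 of 4 shFUT8-1 arrays. Its call in shFUT8-2 was lost without replicate 3 or replicate 4 of that clone. Of 31 genes of NF-kB and inflammatory cytokines, 4 were lower in shFUT8-1 than in shFUT8-2 and 0 higher (median difference -0.11, camera adjusted p = 0.0163, and adjusted p = 0.472 with an estimated correlation). This call was also lost without replicates 1 and 2 of shFUT8-2. Over control, 7 rose and 11 fell in shFUT8-1 and 10 rose and 10 fell in shFUT8-2, and neither was called (camera adjusted p = 0.730 and 0.899). The neutrophil-attracting chemokine genes CXCL8 and CXCL1 fell in both clones, to -3.39 ± 0.13 and -1.90 ± 0.17 in shFUT8-1 and to -2.17 ± 0.38 and -0.98 ± 0.24 in shFUT8-2. CXCL3 was at -1.77 ± 0.50 and -1.57 ± 0.22 (n = 2), and BIRC3, an inhibitor of apoptosis gene, at -1.86 ± 0.32 and -1.94 ± 0.39. Adjusted over the list alone, 5 class I genes rose in shFUT8-2, 5 NF-kB genes were lower in shFUT8-1 than in shFUT8-2 and 11 fell in shFUT8-2, and the other counts were the same. The median of ribosomal protein genes was 0.09 higher in shFUT8-1 (camera adjusted p = 0.00878, and adjusted p = 0.987 with an estimated correlation), with 0 of 63 genes passing. That call was lost with fry, with array weights, without replicate 1 or replicate 3 of shFUT8-1 and without replicate 3 of shFUT8-2. The median difference ran from 0.01 without replicate 1 of shFUT8-1 to 0.28 with median centring. It was 0.18 and 0.16 without replicate 2 or 4 of shFUT8-1, and 0.14, 0.04 and 0.05 without replicate 1, 3 or 4 of shFUT8-2.

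Single genes that differed most between the clones were lower in shFUT8-1 in the case of TNFRSF19, a TNF receptor family gene, which fell to -2.27 ± 0.41 in shFUT8-1 and rose by 1.41 ± 0.29 in shFUT8-2 (SD, n = 4 each), a difference of -3.69 or 12.9-fold. SQOR, a mitochondrial sulfide oxidation enzyme gene, was at -3.45 ± 0.72 and -0.11 ± 0.03, the latter not passing, and SPP1 and AGR2 differed by -3.07 and -3.06. MTHFD2L, AREG, which encodes the EGFR ligand amphiregulin, TLR4, PARM1, OAS2 and MX1 differed by -2.54 to -1.74. The PARM1 difference ran from -3.34 to -1.66 over the settings. In the other direction, DRC11 was at -0.15 ± 0.18 and -2.60 ± 0.36, the former not passing, a difference of 2.45. PTPRK, a receptor tyrosine phosphatase gene, differed by 1.94, the amino acid transporter gene SLC6A15 by 1.66 and BRCA1, a DNA repair gene, by 1.43, with BRCA1 at 1.52 ± 0.19 in shFUT8-1 and 0.09 ± 0.03 in shFUT8-2. ENOX1, MAP7, MAOA, PPP1R9A, SYT14 and KCNMB4 differed by 1.24 to 1.55, and the KCNMB4 call was lost without replicate 3 of shFUT8-2. The SYT14 difference ran from 1.16 to 2.37 over the settings. Other probes were at -1.88 for DRC11 and between -1.49 and -0.79 for PTPRK in shFUT8-2, against -1.68 for the PTPRK probe used, and at 0.67 for MAP7 in shFUT8-1, against 1.48. Each of these genes had a limma adjusted p of 0.0130 or less, and all 4 arrays of one clone lay above those of the other. In total 563 genes differed, 216 higher and 347 lower in shFUT8-1, and 83 of them by 2-fold or more, 24 higher and 59 lower. The number was 366, 343, 371 and 342 without replicate 1, 2, 3 or 4 of shFUT8-2, and 166 without replicates 1 and 2 of that clone. With median centring 718 genes differed, 508 higher and 210 lower, a share of 70.8% against 38.4%, so this balance depends on the normalization, and clone and slide row cannot be told apart in it.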

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

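The tests of second probes, of arrays with different numbers, of the common dye orientation, of single arrays and of the FGF7 probes were chosen only after the results were seen.

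The 4804 genes changed in both clones the same way form the first pattern weighed. A dye effect particular to single probes predicts that a second probe of a gene moves the same way about as often as not, but 90.8% did (1154 of 1271 genes). Where the mean log2 ratio over both clones was 2-fold or more, 98.4% did. Chance deviations of control RNA shared by same-numbered arrays predict a much smaller covariance of the clones over arrays of different numbers, but at least 95.6% of it was kept. Control RNA shared between arrays in another way would pass this split, and the labels do not say which arrays shared it. A dye or control-line effect common to the arrays stays open and cannot be told apart from the knockdown, because the knockdown RNA was in red on all 8 arrays and 1 control line was used. An effect of the knockdown, an effect of vector selection and off-target effects of the hairpins also stay open and were not tested.

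Interferon-stimulated genes had a median of -0.59 for shFUT8-1 minus shFUT8-2, a difference found by the test of the difference itself. Leaving out each of the 8 arrays in turn brought the median no nearer to 0 than -0.55, which argues against 1 array as the source. For this list taken alone, only 1 of the 35 splits of the 8 arrays, the real one, gave a median as far from 0. The highest other split gave 0.40, which argues against chance, but 35 splits allow no smaller share. That count is not adjusted for the choice of this list among 23, and with an estimated correlation the difference did not pass (adjusted p = 0.0645). A shift of probe brightness between the slide rows predicts like medians for other genes of the same brightness. The list lay at percentile 0 of 10000 random lists matched on brightness, with 95% of their medians between -0.07 and 0.06. Loess had already removed shifts by brightness within each array, so these random lists had to centre near 0. The comparison therefore cannot decide on such a shift. A difference in interferon signalling between the clones, whether from the vectors, from clonal selection or from culture, may remain as a candidate explanation and was not tested, nor was any other difference between the slide rows.

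FGF7 was higher in both clones, by 6.17 and 6.32. Hybridisation particular to 1 probe predicts a low ratio at the other FGF7 probe, but that probe was at 3.80 and 3.94. Signal from a near-identical copy of the gene cannot be told apart, because the FGF7P3 probe was also higher, by 3.94 and 3.51, and the related sequences can bind the same transcripts. Which transcript rose, and whether a sequence of the vector or its integration could be involved, was not tested.

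Other splits of the arrays were counted for each comparison. For genes changed in both clones, 1 of 100 sign patterns of the 8 arrays gave as many, the real one with 4804. The highest other gave 38, which argues against chance. For genes differing between the clones, 1 of 35 splits gave as many, the real one with 563. The highest other gave 0, which argues against chance, but 35 splits allow no smaller share. Turned signs and mixed clones also widen the spread within groups, which lowers the other counts. In shFUT8-1 and shFUT8-2 alone, 4 arrays make 8 sign patterns, too few for a share under 0.05; the real numbers were 7232 and 6683, and the highest others 1 and 40. For gene lists, the real numbers in shFUT8-1 and shFUT8-2 were 6 and 4, and the highest others 7 and 5. As many lists were given by 4 and 5 of the 8 patterns, so chance could not be excluded for these numbers. For the median of the ribosomal proteins, 8 patterns are again too few for a share under 0.05. Its real values were 0.329 and 0.205, and the highest others 0.326 and 0.204. For the 4 lists differing between the clones, 24 of 35 splits gave as many and the highest other gave 8, so chance could not be excluded for that number. Taken list by list, 3 of 35 splits gave a median as far from 0 for class I antigen presentation, 2 for NF-kB and inflammatory cytokines and 19 for ribosomal proteins.

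Single arrays stood far from the other 3 of their clone for 12 of 279 sets of 4 values, where chance alone would give 13.95 at 5%. On shFUT8-2 replicate 4, AGR2 was at -1.98 and BRCA1 at 0.040. On shFUT8-2 replicate 3, KIAA0040 was at 2.28, VIM at -0.063, ALCAM at -1.79 and the median of the unfolded protein response list at -0.23. On shFUT8-2 replicate 2, SNAI2 was at -0.38. On shFUT8-1 replicate 4, BRCA1 was at 1.80. On shFUT8-1 replicate 2, ST3GAL6 was at -1.04, SERPINB5 at 1.08, SLC2A3 at 0.14 and the median of the epithelial markers at -0.15.

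The difference between the clones passed its own test for 36 of the 116 genes named and for 4 lists, but for 0 lists with an estimated correlation. Many of these genes had been named because they passed this test. Over all genes, 563 of 17076 passed. Lower in shFUT8-1 were TNFRSF19 by a difference of -3.69, SQOR -3.34, SPP1 -3.07, AGR2 -3.06, MTHFD2L -2.54, AREG -2.39, TLR4 -2.29, PARM1 -1.83, OAS2 -1.76 and MX1 -1.74. Smaller differences in that direction were those of NRP1 at -1.54, THBS1 at -1.31, TIMP3 at -1.22, CXCL8 at -1.22, ADAMTSL3 at -1.12, USP18 at -1.05, CXCL1 at -0.92, ECSCR at -0.88, SORL1 at -0.83, ABCA3 at -0.79, KRT8 at -0.71 and KIAA0040 at -0.63. Higher in shFUT8-1 were DRC11 by 2.45, PTPRK by 1.94, SLC6A15 by 1.66, ENOX1 by 1.55, MAP7 by 1.53, MAOA by 1.44, BRCA1 by 1.43 and PPP1R9A by 1.30. SYT14 was higher by 1.26, KCNMB4 by 1.24, CD44 by 1.21, FAM184A by 1.07, CHGB by 1.00 and PAG1 by 0.79. The list medians differed by -0.59 for interferon-stimulated genes, -0.14 for class I antigen presentation, -0.11 for NF-kB and inflammatory cytokines and 0.086 for ribosomal proteins, with adjusted p = 0.0645, 0.472, 0.472 and 0.987 with an estimated correlation.

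Probes without a gene name were outside the comparisons of genes. Of 13484 such probes, 1724 changed in both clones the same way, 995 up and 729 down, and 688 of 6218 lincRNA probes did, 482 up and 206 down. The probes with the largest mean falls, picked after the values were seen, were A_23_P313632 at -3.52 ± 0.46 and -3.24 ± 0.12 (SD, n = 4 each) and A_23_P48414 at -3.54 ± 0.40 and -2.77 ± 0.12. Among those changed in both clones the same way, the largest mean rise was that of the lincRNA probe A_19_P00315506, at 1.28 ± 0.44 and 1.70 ± 0.28.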

How the results depend on the processing

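Arrays left out in pairs were chosen after seeing the data, as were the extra settings for the correlation of the clones. The correlation kept its value within the spread, between 0.806 and 0.849, in every setting run. Of the values of named genes that passed, 6916 over all settings kept their direction and passed. In 115 cases they kept their direction and no longer passed, and 0 turned. Many of these genes had been chosen for the same sign on all arrays of a clone, so leaving out 1 array could not turn them. Settings that leave a clone's ratios unchanged could not turn them either. For gene lists that passed, 345 held and 29 no longer passed. Among unnamed probes, only those with the largest mean falls and rises called in both clones were followed, and their calls held in all 478 cases. The calls of the other unnamed probes were not followed.

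Requiring 2-fold or more took the numbers of genes to 544 and 474 for shFUT8-1 and shFUT8-2, 321 for both and 83 for the difference. Testing every probe on its own gave 12455, 11332 and 7780 probes, by counting more tests. Leaving out replicates 1 and 2 of shFUT8-2, the arrays with most outlier spots, gave 3684 genes in that clone, 2904 in both and 166 for the difference, a setting with fewer samples; it also ended the shFUT8-2 calls of CD44, CDH2, FCSK, FUT7, HLA-B, RPL21, RPL23, TGFBR1, TGFBR2 and THBS1, the shFUT8-1 calls of CDH1, FUT4 and KCNMB4 and the differences of KCNMB4, MAP7 and the NF-kB list. Leaving out the array least correlated with its clone, replicate 2 of shFUT8-1 and replicate 3 of shFUT8-2, gave 7371, 6198, 4651 and 492. Leaving out 1 array at a time gave 5710 to 7306 genes in shFUT8-1, 5053 to 7255 in shFUT8-2, 3868 to 4766 in both and 342 to 684 for the difference, and 3 to 7 lists for the difference, 7 of them without replicate 4 of shFUT8-1.

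With the replicate number as a fixed replicate block, 311 genes differed between the clones, and 6551, 5894 and 4277 changed in shFUT8-1, shFUT8-2 and both; as a random replicate block the numbers were 7232, 6686, 4805 and 525. The numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.40, -0.05, -0.38 and 0.05, and not every array correlated best with its own number. Same-numbered arrays also lay in the same slide column, so the block describes a shared number and column, which cannot be told apart.

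The number of gene lists passing was 0, 0 and 0 with an estimated correlation and 16, 13 and 7 with fry, for shFUT8-1, shFUT8-2 and the difference; fry tests whether the genes of a list move one way and not whether they differ from other genes. For the difference, 8 lists passed with median centring and 7 with every probe on its own. Directions turned under fry for lung epithelial differentiation in shFUT8-1 (median 0.043) and shFUT8-2 (median 0.061), NF-kB and inflammatory cytokines in shFUT8-2 (median -0.0030) and adhesion and metastasis surface genes in shFUT8-2 (median 0.088), where mean and median lie on different sides of 0 or near it. For the difference of cholesterol biosynthesis, the median without 1 array ran from -0.13 to 0.12, the latter without replicate 2 of shFUT8-1, and was 0.10 without the least correlated arrays. ITGB1 in shFUT8-1 turned to 0.38 with median centring. The cause of these changes was not tested. Aquantile between arrays leaves ratios unchanged by construction, slide as a block could not be fitted, and clones fitted alone give no difference.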

Other observations

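Among 25 genes of lung epithelial differentiation, 5 rose and 5 fell in shFUT8-1 and 7 rose and 6 fell in shFUT8-2, and the list was not called (camera adjusted p = 0.730 and 0.899). ABCA3, the surfactant lipid transporter gene of alveolar cells, fell to -3.18 ± 0.07 and -2.39 ± 0.19 (SD, n = 4 each), and NKX2-1, a transcription factor of lung epithelium, to -0.78 ± 0.20 and -0.92 ± 0.22. NKX2-1 was well above background in red on 1 of 4 shFUT8-1 arrays and 3 of 4 shFUT8-2 arrays, so the sizes depend on the treatment of background, and the scanner log ratios gave -2.56 and -1.97. AGER, a marker of alveolar type 1 cells, rose by 0.72 ± 0.19 and 0.66 ± 0.05. Of 28 p53 targets, 6 rose in each clone and 7 and 8 fell (camera adjusted p = 0.730 and 0.899). SERPINB5, encoding maspin, rose by 1.47 ± 0.27 and 1.87 ± 0.25 and CDKN1A, encoding the cell cycle inhibitor p21, by 0.99 ± 0.28 and 1.07 ± 0.21, while GADD45B fell to -1.22 ± 0.23 and -1.06 ± 0.26 and BTG2 to -0.87 ± 0.14 and -0.73 ± 0.12. Adjusted over the list alone, 8 lung genes and 7 p53 targets rose in shFUT8-2, and the other counts were the same.

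Of 32 genes of hypoxia and glycolysis, 4 rose and 11 fell in shFUT8-1 and 3 rose and 4 fell in shFUT8-2 (camera adjusted p = 0.730 and 0.899), with the carbonic anhydrase gene CA9 at -1.57 ± 0.58 and -1.37 ± 0.14 (SD, n = 4 each) and the glucose transporter gene SLC2A3 up by 0.74 ± 0.40 and 0.93 ± 0.14. Of 45 genes of DNA replication and mitosis, 9 rose and 14 fell in shFUT8-1 and 5 rose and 11 fell in shFUT8-2 (camera adjusted p = 0.955 and 0.899). Of 30 genes of the unfolded protein response, 4 rose and 10 fell, and 3 rose and 8 fell (camera adjusted p = 0.730 and 0.899). Of 26 genes of cholesterol biosynthesis, 2 rose and 5 fell, and 1 rose and 4 fell (camera adjusted p = 0.730 and 0.899), and of 31 immediate early and heat shock genes, 5 rose and 4 fell, and 4 rose and 3 fell (camera adjusted p = 0.730 and 0.496). As a check for cells other than the line, 15 leukocyte markers had 2 up and 1 down in shFUT8-1 and 4 up and 1 down in shFUT8-2 (camera adjusted p = 0.491 and 0.133), and 12 fibroblast and endothelial markers had 1 up and 3 down, and 3 up and 3 down (camera adjusted p = 0.761 and 0.899). Adjusted over the list alone, these counts were the same, except 1 leukocyte marker up in shFUT8-1 and 3 cholesterol genes down in shFUT8-2. The median, the mean and the direction of the list test differed in sign for lung epithelial differentiation in both clones, with medians of 0.043 and 0.061 and means of -0.27 and -0.11. They also differed in shFUT8-1 for fucosylation, mesenchymal markers and immediate early genes, and in shFUT8-2 for NF-kB, hypoxia, p53 targets, surface adhesion genes and fibroblast and endothelial markers, none of them called. For the clone difference the same held for N-glycan processing, epithelial markers, TGF-beta response, replication and p53 targets, again not called.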
